A study of Mus musculus with 2 samples.

How the data were processed

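Both libraries were 10x single-cell RNA libraries of mouse retina, 1 for PBS and 1 for NaIO3, each from 6 pooled mice, per the labels. The deposited files hold raw UMI counts per gene and barcode for 31053 genes, in the authors' filtered Cell Ranger output. Cell Ranger was version 3.0.2 per the file headers, and the build was mm10 per the submitters' processing notes; the annotation version is not given in the sources used here. Of the gene IDs, 30934 are also in the GENCODE M21 annotation, which was used for the positions of 3 genes. Per the labels' protocols retinas were digested with papain, and CD11b beads are named for the NaIO3 pellets alone, although the labels call both libraries CD11b-positive microglia. The values in the PBS library do not settle whether it was selected. Groups were taken from the treatment label.

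Cells were kept with at least 500 UMIs, at least 300 genes and at most 15% of UMIs from mitochondrial genes. This left out 669 of 6242 PBS barcodes, 663 of them over the mitochondrial limit, and 305 of 9746 NaIO3 barcodes. Doublets were called per library with scrublet at an expected rate of 6% and removed. It marked 0 of 5573 PBS cells, so it did not work there, and 180 of 9441 NaIO3 cells (1.91%). Counts were normalised to 10000 per cell and log-transformed with scanpy 1.11.5 under Python 3.11.15, with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Clustering used 2000 variable genes without mitochondrial, ribosomal protein and sex-linked genes, values limited to 10, 30 principal components, 15 neighbours and Leiden resolution 0.8 (igraph 0.11.9), with no integration of the libraries.

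Clusters were named "like" a cell type from markers of 25 types fixed before the data were examined. The scoring was written after the clusters had been seen and was revised more than once. A name needs at least 3 markers at 50 CPM or more, and no other type may score 0.7 of the best score or more or have more markers among the 10 leading genes. Rods also need every other type below a score of 0.15, because rod RNA is free RNA in every cluster. This rule and the marker rules left 88 PBS and 1157 NaIO3 cells unnamed. Immune clusters were pooled and clustered again, a step added after seeing the data. No cluster was named macrophage-like or monocyte-like, although 57 NaIO3 cells were named macrophage-like at 1500 UMIs and 800 genes, so the planned pooling of those with microglia changes nothing.

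Counts were summed over the cells of a class in each library and divided by the class total (CPM). Ratios are NaIO3 over PBS with exact conditional binomial (Clopper-Pearson) 95% intervals, levels have exact Poisson intervals, and shares have exact binomial (Clopper-Pearson) intervals. All cover counting error only. A count of 0 was set at 3 counts, and the resulting fold is a bound, less strict than the lower end of the exact interval. With 1 library per group, no p-value was computed. Counts of genes at least 2 times higher or lower use genes with at least 20 CPM in either library and 20 summed UMIs. To see what counting error alone gives, both libraries were drawn 20 times from the NaIO3 rates. In microglia-like cells 1 PBS UMI is worth 22.8 CPM, in rod-like cells 0.0604 CPM.

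The 22 gene lists, fixed before the data were examined, cover homeostatic and disease-associated microglia, lipid uptake, lipid droplets, cholesterol efflux, cholesterol synthesis, fatty acid oxidation, inflammasome and IL-1, NF-kB targets, interferon response, MHC class I and II, complement, phagocytosis, proliferation, oxidative stress and iron, glycolysis, oxidative phosphorylation, immediate early genes, alternative activation, phototransduction and gliosis. Members with at least 10 CPM in either library were used, and a member counts as higher or lower at 1.5 times. The median was placed among 10000 random lists matched on mean expression in 20 bins, and its interval comes from 200 Poisson redraws, which are poor where PBS counts are 0 or 1. Named genes are Cd36, Nlrp3 and Il1b, then in microglia-like cells the 12 highest and 12 lowest ratios among genes with at least 50 CPM in either library and 50 summed UMIs. Mitochondrial, ribosomal protein, sex-linked and unnamed gene models were left out, as were genes over 5 times higher in another class. Of each list up to 4 members were named, with those going the other way by 1.5 times, and in other classes the 4 highest and 4 lowest genes. Some genes that met these rules are not named. The other classes needed 50 cells in each library; Müller-like cells, with 24 in PBS, were added afterwards. Shares of cells with a UMI use cells thinned to 1000 UMIs.

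In simulated data with 200 genes changed 4 times, 96% of genes made higher and 81% of genes made lower were recovered in the microglia-like comparison (7816 genes), and 100% of both in the rod-like comparison (6760 genes). The alternatives were TMM scaling (edgeR 4.0.16, R 4.3.3), median-of-ratios scaling, mean per-cell CPM, thinned cells, no filter or 100 CPM, genes of other classes left out, 1500 UMIs and 800 genes, 5% or no mitochondrial limit, no doublet removal, resolutions 0.4 and 1.6, microglia-like cells with a P2ry12, Tmem119 or Sall1 UMI, and thinning to 500 or 2000 UMIs. Several more were added after the data were seen. Figures were drawn with matplotlib 3.10.9.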

Results

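Single-cell RNA sequencing (10x droplets) was carried out on retinas of mice given sodium iodate (NaIO3) and of mice given phosphate-buffered saline (PBS). Sodium iodate is an oxidant that damages the retinal pigment epithelium, and photoreceptors degenerate in its wake. The dose was 20 mg per kg into a vein, and retinas were collected on day 7. Each group was 1 library from the pooled retinas of 6 mice, so no difference has a replicate check and no test between the groups was possible. All intervals are 95% intervals that cover counting error only. The PBS library held 6242 barcodes and 26605477 UMIs (unique molecular identifiers, 1 per captured transcript), and the NaIO3 library 9746 barcodes and 75981079 UMIs. After filtering, 5573 PBS cells with a median of 2486 UMIs and 9261 NaIO3 cells with a median of 2930 UMIs were kept.

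The first question was which cell types each library held. Rod-like cells made up 91.5% of kept PBS cells (90.7 to 92.2, exact binomial interval) and 49.1% of kept NaIO3 cells (48.1 to 50.1). That NaIO3 share was 26.0% with doublets kept, 33.3% at 5% mitochondrial UMIs and 33.4% without the highest doublet scores, where 32.6%, 36.7% and 30.5% of cells were unnamed. The PBS share was 65.0% with no mitochondrial limit, where 26.5% were unnamed. Microglia-like cells, named for the resident immune cells of the retina, were 13 of 5573 in PBS, or 0.233% (0.124 to 0.399). In NaIO3 they were 1681 of 9261, or 18.2% (17.4 to 19.0). A P2ry12, Tmem119 or Sall1 UMI was found in 9 of these PBS cells and 736 of these NaIO3 cells. Whether all cells of the class are resident microglia was not tested. Müller-like cells, the main glia of the retina, stood at 0.431% (0.276 to 0.640) in PBS and 6.96% (6.45 to 7.50) in NaIO3. Bipolar-like cells, which relay photoreceptor signals, stood at 1.20% (0.933 to 1.52) and 6.65% (6.15 to 7.18). The labels call both libraries CD11b-positive microglia, but their extraction text describes selection with CD11b beads for the NaIO3 pellets alone. A selection of that kind can by itself set the microglia-like share, and the libraries also differed in depth.

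Cone-like cells were 4.31% of PBS cells (3.79 to 4.87) and 2.67% of NaIO3 cells (2.35 to 3.02), and amacrine-like cells 0.592% (0.408 to 0.831) and 0.885% (0.705 to 1.10), under the same bead selection and depth gap. Endothelial- or pericyte-like cells were 3 in PBS and 162 in NaIO3. Pigment-like cells were 6 and 2, but at 1500 UMIs and 800 genes 16 PBS and 116 NaIO3 cells were named like retinal pigment epithelium. A dendritic-like cluster held 121 NaIO3 cells and 0 PBS cells, which allows a PBS share of up to 0.0662%. Unnamed clusters held 1.58% of PBS and 12.5% of NaIO3 cells. Different clusters held most rods of each library. PBS rods lay mainly in clusters 0, 1 and 4 (2533, 1591 and 937 cells), and NaIO3 rods in clusters 2, 3 and 7 (2121, 1823 and 327 cells). Cluster 3 was led by Edn2 and Fgf2, and cluster 7 by the interferon-response genes Ifit3 and Ifit1.

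**Figure D1:**
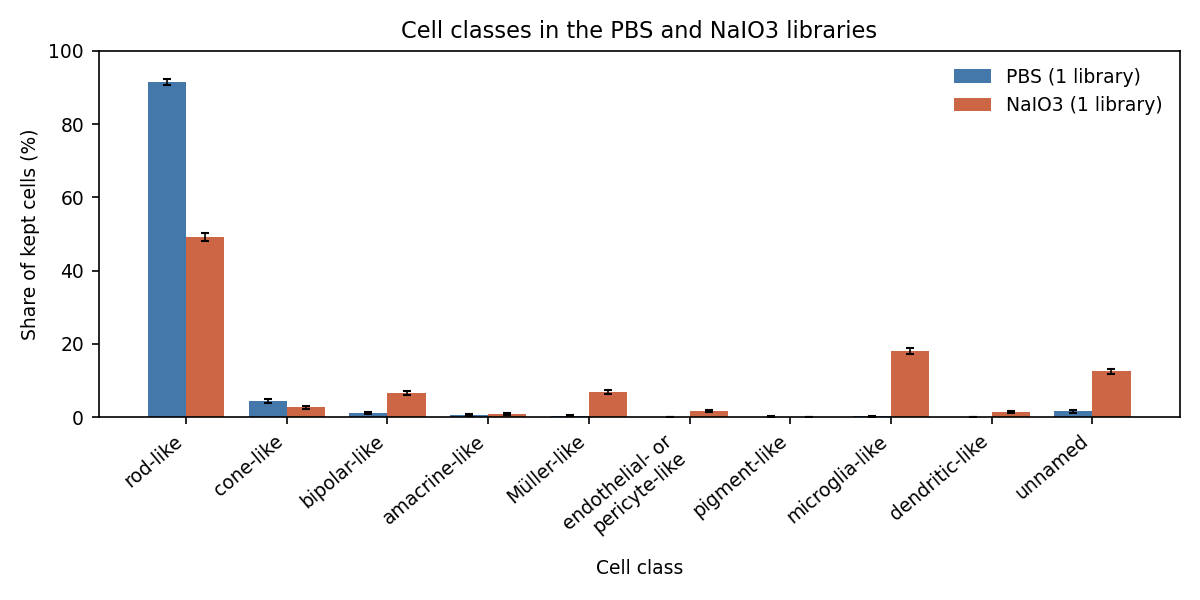
Share of kept cells (%, vertical axis) in each cell class (horizontal axis), with 1 bar per library and exact binomial 95% intervals. Microglia-like cells make up 0.233% of the PBS and 18.2% of the NaIO3 library, with bead selection described for the NaIO3 pellets alone.

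The series title joins Cd36, Nlrp3 and Il1b in reactive microglia, and the next comparison took these genes in microglia-like cells. Cd36, a scavenger receptor that takes up oxidised lipoproteins and fatty acids, had 0 UMIs in the 13 PBS cells and 125 CPM (summed counts scaled to the class total; 120 to 131) in the 1681 NaIO3 cells. Against the floor of 3 counts, 68.3 CPM in PBS, it was at least 1.83-fold higher in NaIO3. The lower end of its exact interval was 1.49. Nlrp3, the sensor of the inflammasome that activates caspase-1, had 1 PBS UMI, 22.8 against 41.0 CPM, a ratio of 1.80 (0.322 to 71.2). Il1b, which encodes the cytokine interleukin-1β, had 2 PBS UMIs, both in 1 cell, and stood at 45.6 against 129 CPM, a ratio of 2.83 (0.783 to 23.4). The intervals for Nlrp3 and Il1b both include a ratio of 1. With TMM scaling the ratios were 2.81 (0.502 to 111) for Nlrp3 and 4.42 (1.22 to 36.5) for Il1b, so whether the Il1b interval leaves out 1 depends on the scaling. Among cells of at least 1500 UMIs and 800 genes, where 3 PBS and 444 NaIO3 microglia-like cells were left, the Nlrp3 log2 ratio was −0.26. Cd36 gave no usable fold there. Il1b was also over 5 times higher in the dendritic-like cells of the NaIO3 library, at 835 CPM.

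On mm10 with GENCODE annotation, the protein-coding genes lie as follows. Cd36 (ENSMUSG00000002944) is on chromosome 5 from 17781690 to 17888801, minus strand. Nlrp3 (ENSMUSG00000032691) is on chromosome 11 from 59541568 to 59566956, plus strand. Il1b (ENSMUSG00000027398) is on chromosome 2 from 129364570 to 129371139, minus strand.

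**Figure D2:**
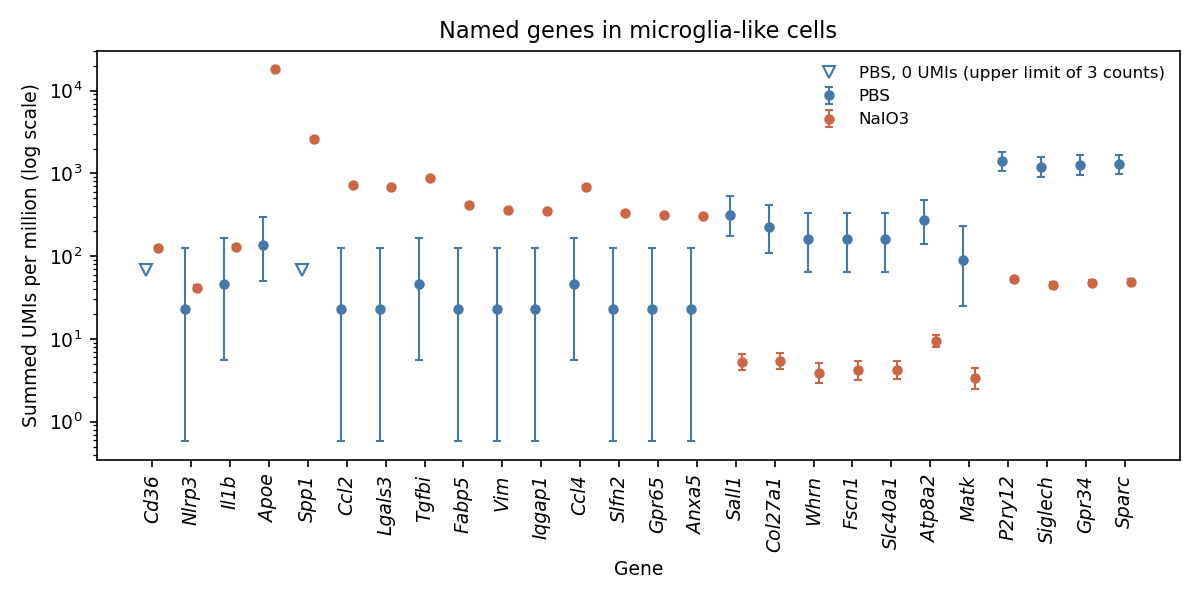
Summed counts scaled to the class total (CPM, log axis) of each named gene (horizontal axis) in PBS and NaIO3 microglia-like cells, 1 library each, with exact Poisson 95% intervals and an open triangle at the 3-count floor where PBS had 0 UMIs. Cd36 stands at 125 CPM in NaIO3 against a PBS floor of 68.3 CPM, and P2ry12 at 1412 CPM in PBS against 52.3 CPM in NaIO3.

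In single cells thinned to 1000 UMIs, 9.05% of 1249 NaIO3 microglia-like cells had a Cd36 UMI (7.51 to 10.8), 2.88% an Nlrp3 UMI (2.03 to 3.97) and 5.12% an Il1b UMI (3.97 to 6.50). Thinning left out 432 shallower NaIO3 cells and 5 PBS cells. None of the 8 remaining PBS cells had a UMI of any of these genes, which allows up to 36.9%. Without thinning, the NaIO3 shares were 26.7%, 17.3% and 13.4%, and the PBS shares 0 of 13, 1 of 13 and 1 of 13. NaIO3 rod-like cells, which should lack these genes, gave 0.0938% for Cd36, 0.0703% for Nlrp3 and 0.188% for Il1b at the same thinned depth. The median depth before thinning was 3665 UMIs in those microglia-like and 2733 UMIs in those rod-like cells.

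Whether Il1b and Nlrp3 went with Cd36 from cell to cell was asked within the NaIO3 library. With all UMIs, 30.1% of the 448 cells with a Cd36 UMI had an Il1b UMI (25.9 to 34.6), against 7.38% of the 1233 cells without (5.98 to 8.98). For Nlrp3 the shares were 37.7% (33.2 to 42.4) and 9.81% (8.21 to 11.6). For Plin2, a coat protein of lipid droplets, they were 65.6% (61.0 to 70.0) and 28.1% (25.6 to 30.7). The cells with a Cd36 UMI had a median of 15030.5 UMIs and those without 1452, so a UMI of any gene was more often seen in the former. At 1000 UMIs per cell the Il1b shares were 7.08% (3.11 to 13.5) and 4.93% (3.74 to 6.35). Those of Nlrp3 were 3.54% (0.973 to 8.82) and 2.82% (1.93 to 3.95), and those of Plin2 11.5% (6.27 to 18.9) and 14.3% (12.3 to 16.4). At equal depth these intervals overlapped. Thinning left 113 cells with a Cd36 UMI, so cells that had one before thinning could count as without. The 2 groups also differed in depth before thinning, at medians of 2819 UMIs with Cd36 and 3751 UMIs without. The overlap therefore does not exclude a link between Cd36 and these genes. Apoe was found in 93.8% and 95.2% of these thinned cells, and P2ry12 in 7.08% and 4.40%.

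**Figure D3:**
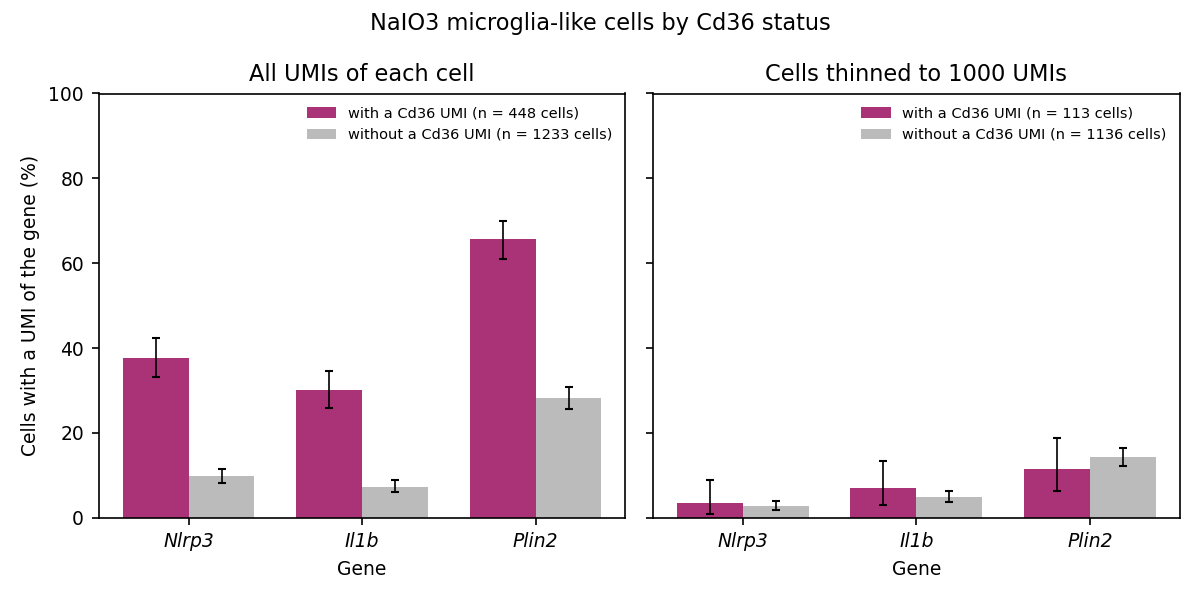
Share of NaIO3 microglia-like cells with a UMI of Nlrp3, Il1b or Plin2 (%, vertical axis), split by whether the cell had a Cd36 UMI, with exact binomial 95% intervals. With all UMIs the Il1b shares are 30.1% and 7.38%, and at 1000 UMIs per cell 7.08% and 4.93%.

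Across the transcriptome of microglia-like cells, Apoe, which carries cholesterol between cells, had the highest ratio among the named genes. It stood at 137 CPM in PBS and 18038 CPM in NaIO3, 132-fold higher (60.6 to 360), and 5 of its 6 PBS UMIs lay in 1 cell. Spp1 (osteopontin) had 0 PBS UMIs and 2626 CPM in NaIO3, at least 38.4-fold higher. The chemokine genes Ccl2 and Ccl4 had ratios of 31.7 (5.69 to 1253) and 14.9 (4.11 to 123), on 1 and 2 PBS UMIs. Lgals3 (galectin-3, 29.8, 5.35 to 1178), the fatty acid binding protein gene Fabp5 (18.2, 3.26 to 718) and Tgfbi (19.2, 5.31 to 159) had 1, 1 and 2 PBS UMIs. Vim (364 CPM), Iqgap1 (15.4), Slfn2 (14.5), Gpr65 (13.6) and Anxa5 (13.5) rested on 1 PBS UMI each, with lower bounds between 2.43 and 2.87.

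The genes that were lowest in NaIO3 included markers of resting microglia. Sall1, a transcription factor of microglial identity, stood at 319 CPM in PBS and 5.29 CPM in NaIO3, 60.3-fold lower (31.5 to 108). P2ry12, a purine receptor, was 27.0-fold lower (20.5 to 35.0), Siglech 26.8-fold (19.8 to 35.5), Gpr34 26.7-fold (20.0 to 35.1) and Sparc 26.3-fold (19.7 to 34.5). Slc40a1, the iron exporter ferroportin, was 37.6-fold lower (14.5 to 82.2). Col27a1 (42.0-fold), Whrn (40.9-fold), Fscn1 (38.2-fold), Atp8a2 (28.9-fold) and Matk (27.3-fold) rested on 4 to 12 PBS UMIs. Several of these genes had also served to name the class. A different make-up of the class was not separated from lower expression within it. Of the 13 PBS cells 8 lay in immune sub-cluster 0, which held 427 of the 1681 NaIO3 cells, sub-clusters 4 and 5 held 0 PBS cells and 110 and 225 NaIO3 cells, and in sub-cluster 2 markers of tissue macrophages scored 0.497 against 0.828 for microglia.

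By size alone, 767 of 8231 genes were at least 2 times higher in NaIO3 microglia-like cells and 2604 at least 2 times lower. Of the higher genes 57 were at a bound, and 1017 of the 8231 had no usable fold. The PBS side held only 43901 UMIs against 14375646, and 1748 of the lower genes had 1 to 3 PBS UMIs. Draws with no difference, at the NaIO3 rates, gave 438 higher and 1589 lower genes of 7832 on average, so most of these counts are at a level that counting error alone gives. With TMM scaling the counts were 1752 and 1036, which moves the higher share from 22.8% to 62.8% and the median of all genes by 0.88 on the log2 scale. With the mean of per-cell CPM they were 1560 and 1450, a higher share of 51.8% and a shift of 0.61.

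Gene lists fixed beforehand were then compared in microglia-like cells, each by the median log2 ratio of its measured members, its percentile among 10000 matched random lists, and the ratio of summed CPM. The median changed sign in 11 of the 22 lists with TMM scaling and in 8 with the mean of per-cell CPM. Homeostatic microglia genes were lower, with 18 of 19 members at least 1.5 times lower and 1 higher, a median of −2.05 (percentile 0) and a sum at 0.241 of the PBS level (0.227 to 0.257). Besides Sall1 and P2ry12, Crybb1 was at 0.0158 and the fructose transporter gene Slc2a5 at 0.0237 of PBS, while Fcrls was at 2.11 (0.902 to 6.49). Disease-associated microglia genes went both ways, with a median of 0.01 (percentile 87.8) and a sum 2.28-fold higher (2.11 to 2.46). Apoe, Spp1, Lgals3 and Fabp5 led it, whereas the lipid receptor gene Trem2 was at 0.251 (0.203 to 0.314), Cd9 at 0.152, and the cathepsin genes Ctsl and Ctsz at 0.229 and 0.620.

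The lipid lists were mixed. Of 11 measured uptake and carrier genes, 5 were higher and 4 lower, with a median of −0.37 (percentile 84.6) and sums of 478 and 1099 CPM, a ratio of 2.30. Msr1, another scavenger receptor, had 0 PBS UMIs and was at least 1.98-fold higher, and Lrp1 and Lpl had ratios of 2.47 (0.965 to 9.08) and 2.52 (0.698 to 20.9). Fabp4 was at 0.0565, Scarb1 at 0.215 and Vldlr at 0.348 (0.0953 to 2.89). Lipid droplet and triglyceride genes had 4 of 14 higher and 5 lower, a median of −0.60 (percentile 76.0) and a summed ratio of 1.53 (1.03 to 2.38). Plin2 had a ratio of 4.43 (1.23 to 36.6), Plin3 1.53, Soat1, which esterifies cholesterol, 2.07 (0.807 to 7.60) and the lysosomal lipase gene Lipa 2.52 (0.860 to 12.2). Mgll was at 0.102, Dgat1 at 0.191, Hilpda at 0.226 and Acsl3 at 0.497. The medians of both lists changed sign with TMM scaling, at 0.27 and 0.042, and with the mean of per-cell CPM, at 0.41 and 0.35.

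Cholesterol efflux and LXR target genes had a median of −0.05 (percentile 90.7) and a summed ratio of 16.3 (12.4 to 21.7), most of it Apoe, and a median of 0.59 with TMM scaling. The exporter genes Abca1 (0 PBS UMIs, at least 3.22-fold) and Abcg1 (4.23, 0.758 to 167) were on the higher side, and Lpcat3 (0.264), Nr1h2 (0.519) and Mylip (0.774) on the lower. Cholesterol synthesis genes were lower, with 13 of 16 at least 1.5 times lower and 0 higher, a median of −1.83 (percentile 1.37) and a summed ratio of 0.367 (0.250 to 0.562). The list held 26 PBS UMIs in all, each worth 22.8 CPM, and 3 members had no usable fold and could not count as higher. The member counts and ratios are therefore partly set by the floor. With TMM scaling the summed ratio was 0.572 (0.390 to 0.877). Msmo1 was at 0.114 (0.0513 to 0.313), Mvd at 0.104, Hsd17b7 at 0.110 and Sqle at 0.119. Fatty acid oxidation genes had 4 of 17 higher and 6 lower, a median of −0.56 (percentile 52.2) and a summed ratio of 0.877 (0.646 to 1.22), which with TMM scaling were 0.081 and 1.37 (1.01 to 1.91). Among them Cpt1a, the gate of mitochondrial fatty acid entry, had a ratio of 2.32 (0.416 to 91.9), Acadl 1.55, Etfa 1.57 and Etfb 5.21, against Cpt2 at 0.218, Hadhb at 0.240, Echs1 at 0.474 and Acadm at 0.479.

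Inflammasome and IL-1 genes had 4 of 17 higher and 6 lower, a median of −0.96 (percentile 42.2) and a summed ratio of 0.806 (0.631 to 1.05). Of these members 5 had no usable fold and entered the median at the floor, and with TMM scaling the summed ratio was 1.26 (0.984 to 1.63). The members other than Nlrp3 and Il1b on the higher side were Aim2 (1.51, 0.417 to 12.5) and Myd88 (2.34, 0.419 to 92.6). On the lower side, Nek7, a partner of Nlrp3, was at 0.399 (0.216 to 0.834), the gasdermin gene Gsdmd at 0.499 (0.194 to 1.84), Txnip at 0.481 (0.275 to 0.934) and Nlrp1b at 0.417. NF-kB target, cytokine and chemokine genes had 9 of 17 higher and 6 lower, a median of 1.22 (percentile 100) and a summed ratio of 2.62 (2.08 to 3.36). Its higher side held the chemokine genes Ccl2, Ccl4, Ccl12 (7.65, 2.99 to 28.1) and Cxcl16 (11.8, 3.26 to 97.3). Its lower side held Nfkbia (0.237, 0.155 to 0.384), Icam1 (0.372), Relb (0.282), Rela (0.602), Nfkb1 (0.628) and Tnfaip3 (0.641). This median was −0.20 with the mean of per-cell CPM.

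Interferon-response genes were higher, with 12 of 19 at least 1.5 times higher and 0 lower, a median of 1.02 (percentile 100) and a summed ratio of 9.70 (6.62 to 14.8). In this list 11 members were at a bound and 3 had no usable fold, so the median is mostly set by the floor. Ifitm3 and Ifi204 had 0 PBS UMIs and were at least 13.3-fold and 5.64-fold higher. Ifi27l2a and Bst2 had ratios of 6.16 (3.60 to 11.6) and 5.35 (2.72 to 12.4). MHC class II genes, which present antigen to helper T cells, had a median of 0.37 (percentile 94.5) and a summed ratio of 2.62 (2.16 to 3.21), with Cd74 at 4.11 (2.82 to 6.24), H2-Aa at 4.03 (all 12 PBS UMIs in 1 cell), H2-Ab1 at 2.38, H2-Eb1 at 1.71 and H2-Oa at 0.565. Of the 8 members, 6 were over 5 times higher in another class, and the median was −0.23 with the mean of per-cell CPM. MHC class I genes had a median of 0.62 (percentile 94.9) and a summed ratio of 1.26 (1.12 to 1.43), with H2-K1 at 1.69 (1.19 to 2.51), Psmb9 at 1.89, H2-Q7 at 1.97 and Tap2 at 1.79. Proliferation genes had a sum of 6 PBS UMIs and a ratio of 19.0 (8.72 to 51.7), with a median of 0.47 (percentile 100). Of its 20 members 10 were at a bound and 8 had no usable fold, so this median and its percentile are mostly set by the floor. Mki67, Top2a and Stmn1 had 0 PBS UMIs and stood at 341, 448 and 348 CPM in NaIO3, the latter 2 at least 6.55- and 5.09-fold higher, and Ccnb2 had a ratio of 3.44 (0.617 to 136).

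Complement genes had a median of −0.48 (percentile 36.5) and a summed ratio of 0.654 (0.609 to 0.703), with C1qa at 0.568 (0.505 to 0.640), C1qb at 0.657, C1qc at 0.719 and Itgb2 at 2.27 (0.885 to 8.33). With TMM scaling the median was 0.17 and the summed ratio 1.02, with an interval that includes 1. Phagocytosis and lysosome genes had a median of −0.31 (percentile 29.6) and a summed ratio of 0.748 (0.705 to 0.795), which with TMM scaling were 0.33 and 1.17 (1.10 to 1.24). Ctsl was at 0.229, Hexa at 0.444 and Mertk at 0.406, against Ctsb at 2.83 (2.07 to 3.98), Grn at 1.95, Cd68 at 1.86 and Axl, a receptor for dying cells, at 0 PBS UMIs and at least 3.84-fold higher. Oxidative stress and iron genes had a median of −0.26 (percentile 64.5) and a summed ratio of 1.92 (1.74 to 2.13), the median being 0.38 with TMM scaling. The ferritin genes Fth1 and Ftl1 had ratios of 1.73 (1.52 to 1.98) and 2.40 (1.96 to 2.97), Prdx1 4.05, Gpx1 2.45, Sod1 5.59 and Hmox1 3.72 (0.667 to 147), against Slc40a1, Cat (0.606), Sod2 (0.625) and Gclc (0.748).

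Nuclear oxidative phosphorylation genes had 13 of 24 members higher and 1 lower, a median of 0.63 (percentile 99.4) and a summed ratio of 1.58 (1.40 to 1.78). Uqcrq was at 5.71, Atp5b at 3.14, Ndufs5 at 3.04, Ndufa2 at 2.24 and Ndufb3 at 0.629. Glycolysis genes had a median of −0.20 (percentile 40.1) and a summed ratio of 1.17 (1.01 to 1.37), the median being 0.44 with TMM scaling, with Gapdh at 2.11 and Ldha at 1.85 against Pfkl at 0.251, Slc2a1 at 0.254, Hk2 at 0.658 and Pfkp at 0.683. Immediate early and dissociation genes had a median of −0.60 (percentile 8.21) and a summed ratio of 0.646 (0.595 to 0.702), which with TMM scaling were 0.041 and 1.01 (0.928 to 1.10). Jund (0.181), Rhob (0.270), Junb (0.336) and Btg2 (0.354) were on the lower side, and Dusp1 (6.72), Atf3 (2.72), Fosb (2.48), Fos (1.87), Klf6 (1.69) and Hspa1a (0 PBS UMIs, at least 1.54-fold) on the higher. Alternative activation and growth factor genes had a median of −0.30 (percentile 76.4) and a summed ratio of 0.956 (0.642 to 1.49), with Pdgfb at 0.274 and Il4ra at 0.811, and a median of 0.34 with TMM scaling. The gliosis list had a median of −0.19 (percentile 93.6) and a summed ratio of 1.51 (1.03 to 2.32), with Vim on the higher side and Glul at 0.618, Rlbp1 at 0.767, Nes at 0.877 and Stat3 at 0.968, and a median of 0.26 with TMM scaling.

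Rod transcripts marked free RNA in these cells. The phototransduction list summed to 13895 CPM in PBS and 2196 CPM in NaIO3 microglia-like cells, a ratio of 0.158 (0.146 to 0.172) and a median of −2.84 (percentile 0), with Prph2 at 0.0998, Nrl at 0.0928 and Pdc at 0.100. Other genes therefore took a smaller part of the PBS total. The whole comparison rests on 13 PBS cells.

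Rod-like cells of the NaIO3 library had less phototransduction RNA and more interferon, MHC class I and immediate early RNA. The phototransduction list had a median of −0.75 (percentile 0.010) and summed to 0.510 of the PBS level (0.508 to 0.511). In it 8 of 15 genes were at least 1.5 times lower and 0 higher, with Pdc at 0.335, Pde6g at 0.347 and Prph2 at 0.367. Glycolysis genes had a median of −0.67 (percentile 0) with 10 of 16 lower and 1 higher, among them Pgam1 at 0.298, Pfkl at 0.350, Eno1 at 0.369 and the lactate transporter gene Slc16a3 at 0.165, against Hk1 at 1.83. These values compare PBS rods mainly of clusters 0, 1 and 4 with NaIO3 rods mainly of clusters 2, 3 and 7. Mitochondrial transcripts were 7.86% of UMIs in PBS rods and 2.49% in NaIO3 rods.

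All 11 measured interferon-response genes were higher in NaIO3 rods, with a median of 5.73 (percentile 100) and a summed ratio of 11.0 (10.4 to 11.7). The antiviral genes Ifit1 and Ifit3 had ratios of 575 (159 to 4757) and 373 (145 to 1370.4) on 2 and 4 PBS UMIs, and Oasl2 132 (60.3 to 361). Cluster 7, with 327 of the 4548 NaIO3 rods, held 1083 of their 1453 Ifit3 UMIs, at 805 CPM against 16.8 and 30.1 CPM in clusters 2 and 3, and without it the interferon response median in rod-like cells was 5.43. All 10 MHC class I genes were higher, with a median of 5.67 (percentile 100) and sums of 93.3 and 1119 CPM, B2m having 1.39 and 134 CPM. In these lists, 7 and 4 members were over 5 times higher in another class. C1qa, a microglial gene that read free RNA in rods, stood at 1.81 and 16.7 CPM. Immediate early genes had 13 of 18 higher and 1 lower, a median of 1.05 (percentile 100) and a summed ratio of 3.27 (3.22 to 3.32), with Fos at 10.5 (10.0 to 11.0), Fosb at 32.1, Junb at 11.3, Socs3 at 423 (165 to 1553) and Hspa1a at 0.601. The gliosis list, which includes the injury factors Edn2 (61.9, 47.3 to 82.6) and Fgf2 (20.0, 18.0 to 22.4), had a median of 1.92 (percentile 100), with Stat3 at 7.55, Cp at 8.35 and Rlbp1 at 0.459.

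Among genes with at least 50 CPM in either library and not over 5 times higher in another class, the highest ratios in rods were those of Bcl3 (70.9 CPM in NaIO3), H2-Q7 (62.3 CPM) and Gbp7 (61.1 CPM), each with 1 PBS UMI and lower bounds of 210, 185 and 181, and of Socs3, a feedback inhibitor of cytokine signalling. The lowest were Slc22a29 (13.8-fold lower, 10.7 to 17.9), Slc16a3 (6.04-fold), Wisp1 (5.30-fold) and Rncr4 (4.78-fold). Cd36, Nlrp3 and Il1b had 2, 1 and 1 UMIs in PBS rods and 8, 6 and 16 in NaIO3 rods. By size, 765 of 7165 genes were at least 2 times higher and 214 at least 2 times lower, a higher share of 78.1%. Draws with no difference gave 0 and 0. With TMM scaling, which moved the median of all genes from 0.29 to −0.08, the counts were 347 and 527, a higher share of 39.7%, and with median-of-ratios scaling 419 and 373 (a shift of −0.26 in the median of all genes, a higher share of 52.9%). The phototransduction median was −1.09 and the interferon response median 5.85 with TMM scaling, so both kept their direction.

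Cone-like cells (240 PBS, 247 NaIO3), all of cluster 5, differed in the same lists. The phototransduction list had a median of −0.95 (percentile 0) with 10 of 15 lower, among them Gngt1 at 0.280, Pdc at 0.304 and Pde6g at 0.345. These are mostly rod genes, and the list summed to 82308 CPM in PBS cones against 104045 CPM in PBS rods. Glycolysis had a median of −0.58 (percentile 0.010), with Slc16a3 at 0.166, Pgam1 at 0.324, Pdk1 at 0.378 and Pfkl at 0.395. Interferon-response genes had a median of 4.49 (percentile 100), MHC class I 3.05 (percentile 100) and immediate early genes 1.29 (percentile 100), with Fos at 15.5 (14.0 to 17.3). The gliosis list had a median of 2.32 (percentile 100). In the interferon and MHC class I lists 9 of 11 and 8 of 10 members were over 5 times higher in another class, and C1qa stood at 0 and 12.5 CPM. Without such genes the interferon response median in cone-like cells was 1.51, and in thinned cells, where the floor for PBS counts of 0 lies higher, 0.39.

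Edn2, which codes for endothelin-2, had 0 PBS UMIs and 114 CPM in NaIO3 cones, at least 201-fold higher, and Bcl3 was at least 95.5-fold higher. Cebpd had a ratio of 118 (57.1 to 296) and Fgf2os 75.5 (29.0 to 280). The lowest among genes with at least 50 CPM in either library were Tmlhe (5.04-fold lower) and Wisp1 (4.80-fold). By size, 599 of 7232 genes were higher and 155 lower, a higher share of 79.4%, and with TMM scaling 308 and 334, a higher share of 48.0%. TMM scaling moved the median of all genes by −0.30, and median-of-ratios scaling by −0.22, with a higher share of 56.9%.

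Bipolar-like cells (67 PBS, 616 NaIO3, clusters 8 and 9) went the other way in the phototransduction list, with a median of 1.46 (percentile 100) and 14 of 15 members higher, such as Nr2e3 (10.9, 7.19 to 17.4), Pde6b (6.65), Sag (5.54) and Pde6a (5.25). That median was −0.76 at Leiden resolution 0.4, where 18 PBS cells were left in the class. Glycolysis had a median of −0.64 (percentile 0.010), with Slc16a3 at 0.332, Pgam1 at 0.415, Pfkl at 0.436 and Eno1 at 0.483, against Hk1 at 1.54 and Hk2 at 2.54. Cholesterol synthesis had a median of −0.47 (percentile 1.02), with Fdps at 0.293, Idi1 at 0.326, Insig1 at 0.347 and Srebf2 at 0.377. MHC class I genes had a median of 2.37 (percentile 100), interferon-response genes 0.87 (percentile 99.0), immediate early genes 1.59 (percentile 100) and the gliosis list 1.79 (percentile 100). With cells thinned to 1000 UMIs these 4 medians were −0.13, −1.42, −0.020 and −0.49, and 6 of 8 MHC class I and 9 of 11 interferon-response members were over 5 times higher in another class. Thinning also raises the CPM floor at which PBS counts of 0 are set, which lowers the ratios of such members. The thinned medians therefore cannot tell a change of direction from an effect of the floor.

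Fgf2, a growth factor that protects photoreceptors, had 1 PBS UMI and 179 CPM in NaIO3 bipolar-like cells, a ratio of 94.9 (17.0 to 3753). Serpina3n, a protease inhibitor of reactive glia, was at least 45.4-fold higher, and Cerkl and Cfi had ratios of 43.1 (7.70 to 1706) and 32.5 (5.80 to 1289). Mir670hg was 12.2-fold lower (8.36 to 17.7), Dusp15 7.33-fold (4.38 to 12.1), Thrsp 6.66-fold (4.83 to 9.12) and Smim18 6.26-fold (4.06 to 9.52). By size, 948 of 7976 genes were higher and 568 lower, against 63.7 and 33.1 in draws with no difference.

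**Figure D4:**
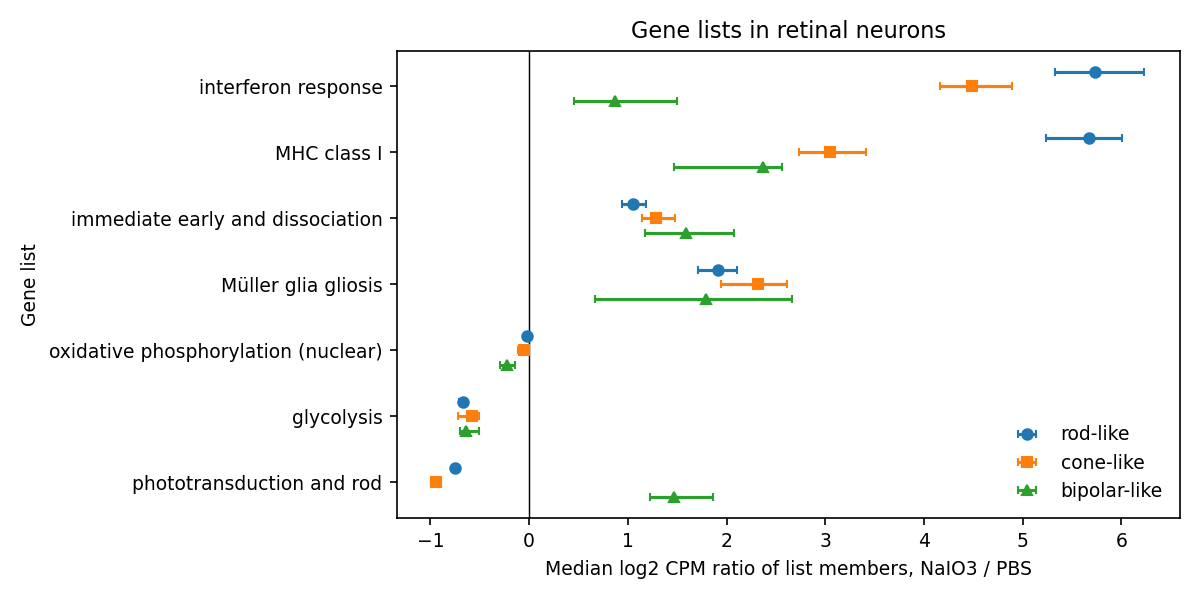
Median log2 ratio of CPM, NaIO3 over PBS (horizontal axis), of 7 gene lists (vertical axis) in rod-, cone- and bipolar-like cells, with 95% intervals from redrawn counts. The interferon medians are 5.73, 4.49 and 0.87, and the phototransduction medians −0.75, −0.95 and 1.46.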

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

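The clusters described here were picked after the clusters had been seen, and none of them was part of a planned comparison.

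A dendritic-like cluster held 1.31% of kept NaIO3 cells (1.09 to 1.56) and 0 of 5573 PBS cells, which allows up to 0.0662%. It lies outside the comparisons between the groups and was set apart because its NaIO3 share exceeds that limit. No cluster was named dendritic-like at 1500 UMIs and 800 genes, at 5% mitochondrial UMIs, without the highest doublet scores or without the second clustering. Its cells had the highest Il1b level of the immune clusters of the NaIO3 library, 835 CPM (799 to 873), beside 7044 CPM of the MHC class II gene H2-Aa and 60.5 CPM of the dendritic receptor gene Flt3. Immune sub-cluster 6 held 2.03% of kept NaIO3 cells (1.75 to 2.34) and 0 PBS cells. It combined the lymphocyte genes Xcl1 (966 CPM), Gzma (464 CPM) and Nkg7 (420 CPM) with C1qa (2079 CPM), and more microglial than lymphoid markers were among its leading genes, so it stayed unnamed. Its median of 31462 UMIs was the highest of all clusters. Cluster 6, led by haemoglobin genes together with rod genes, held 7.53% of kept NaIO3 cells and 0.861% of PBS cells (0.636 to 1.14), at a median of 1005 UMIs, with Hbb-bs at 2325 CPM in NaIO3 and 0 UMIs in PBS. Bead selection is described for the NaIO3 pellets alone and the libraries differ in depth, so these shares do not compare the retinas.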

How the results depend on the processing

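The alternatives on second clustering of immune cells, on the highest doublet scores and on single rod clusters were chosen after the data were seen, as was the Müller-like class. Of 283 alternative values of the main results 201 stayed within their limits and 82 moved. Resolutions 0.4 and 1.6 returned the same 13 PBS and 1681 NaIO3 microglia-like cells, since immune cells were clustered again at 0.8 in both. Their microglia-like values are counted among the 201 but are no check on that class. In microglia-like cells the Nlrp3 log2 ratio of 0.85 was −0.26 at 1500 UMIs and 800 genes, inside its wide interval, where Cd36 gave no usable fold, and the Il1b log2 ratio was 0.46 there. That setting left 3 PBS microglia-like cells. None of the 3 gave a usable fold in thinned cells. The rule for calling a list median reversed was tightened 2 times after its outcome had been seen. Asking only for an interval without 0, 88 of 1503 list medians reversed. Asking also that the median lie outside the central 95% of random lists left 21. Leaving out 32 medians that rest on members without a usable fold, 11 of which had reversed under the first rule, left 16 of 1471. In the microglia-like comparison 1 PBS UMI is 22.8 CPM. No paired analysis was possible because each group has 1 library and the results come from no test, and no replicate could be left out. Bipolar-like cells had 0 PBS cells at 5% mitochondrial UMIs, so that setting gives no value. Unless stated, the cause was not tested.

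The amacrine-like fold per rod-like cell of 2.79 reversed to 0.313 at 1500 UMIs and 800 genes. The microglia-like share of 0.233% in PBS was 0.0647% at 1500 UMIs and 800 genes. That of 18.2% in NaIO3 was 6.12% there, 17.0% with no mitochondrial limit, 16.8% without the highest 6% of doublet scores and 21.8% without the second clustering. The Cd36 share of 9.05% was 5.59% at 500 UMIs, 15.6% at 2000 UMIs, 26.7% unthinned and 11.1% with no mitochondrial limit. The Nlrp3 share of 2.88% was 1.01%, 5.68% and 17.3% in the first 3 of these, and 1.80% without the highest doublet scores. The Il1b share of 5.12% was 2.74%, 12.2% and 13.4%, and 11.3% at 1500 UMIs and 800 genes, 9.23% without the second clustering and 7.98% in cells with a P2ry12, Tmem119 or Sall1 UMI. Thinning changes these shares by its construction. The Il1b share of 7.08% with Cd36 was 30.1% unthinned. The share of 4.93% without Cd36 was 2.71%, 12.6% and 7.38% at 500 UMIs, 2000 UMIs and unthinned, 11.7% at 1500 UMIs and 800 genes, 9.47% without the second clustering and 7.99% in cells with one of the named microglial UMIs.

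Genes at least 2 times higher in microglia-like cells, 767, were 1752 with TMM scaling, 1560 with mean per-cell CPM, 147 thinned, 421 at 100 CPM and 368 at 1500 UMIs and 800 genes. The lower ones, 2604, were 1036, 1450, 1268 and 621 in the first 4 of these, and 1690 with no mitochondrial limit. In rods, 765 higher genes were 419 with median-of-ratios scaling, 347 with TMM, 3662 unfiltered, 267 at 100 CPM, 482 at 5% mitochondrial UMIs and 1286 without PBS cluster 0, and 214 lower genes were 373, 527, 919, 86 and 474, and 439 against PBS cluster 0 only. In cones, 599 higher genes were 341, 308, 2497, 181 and 1470, and 155 lower genes 258, 334, 652, 70 and 452, in the first 5 of those settings, and 236 thinned. In bipolar-like cells, 948 higher genes were 1613 unfiltered and 264 at 100 CPM, and 568 lower genes 2039 and 139, and 278 with no mitochondrial limit. Counts under other filters differ by construction, since they test other numbers of genes.

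In microglia-like cells the lipid uptake median of −0.37 was 0.27 with TMM scaling, 0.41 with mean per-cell CPM, 0.87 without genes of other classes, 1.14 at 100 CPM, −0.14 with no mitochondrial limit and −0.16 with doublets kept. The lipid droplet median of −0.60 was 0.042, 0.35, −0.19, 1.33, −0.33 and −0.21 in these, −0.52 with median-of-ratios scaling, −1.60 at 1500 UMIs and 800 genes and −0.54 without the highest doublet scores. The inflammasome and IL-1 median in microglia-like cells of −0.96 was −0.34 with TMM scaling, −1.29 at 1500 UMIs and 800 genes and −1.28 with at most 5% mitochondrial UMIs. The NF-kB median of 1.22 reversed to −0.20 with mean per-cell CPM.

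In bipolar-like cells, resolution 0.4 reversed Smim18 (0.082), cholesterol efflux (−0.26) and phototransduction (−0.76), and thinning reversed interferon response (−1.42), MHC class I (−0.13), immediate early genes (−0.020) and gliosis (−0.49). In Müller-like cells, resolution 0.4 reversed Abca4 (−0.28) and phototransduction (−0.22). Thinning to 1000 UMIs reversed the interferon response (−0.17) and homeostatic microglia (−1.07) lists, and the disease-associated microglia median in Müller-like cells became −1.04. With 67 PBS bipolar-like and 24 PBS Müller-like cells, thinned totals are small, and the 3-count floor lies higher in CPM than in the main comparison. The sign changes under thinning may therefore come from the floor. The homeostatic list was also −1.45 unfiltered and −0.091 with no mitochondrial limit, and the disease-associated list −0.53 unfiltered, −0.78 without genes of other classes and −0.81 at 100 CPM.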

Other observations

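The tests of cell numbers, of nuclear RNA and of counting depth were chosen after the result was seen, while the tests of a few dominant genes, of RNA shared by every class, of dendritic doublets and of free RNA in shallow cells were written before.

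Müller-like cells (24 PBS, 645 NaIO3) were compared after the data were seen. Lcn2, an iron-binding protein of reactive glia, had a ratio of 188 (51.9 to 1549) on 2 PBS UMIs. Interferon-response genes had a median of 2.01, with 13 of 15 higher and 1 lower, immediate early genes 1.91 and MHC class I genes 1.56. The interferon median was −0.17 in cells thinned to 1000 UMIs, where the floor for PBS counts of 0 lies higher. Cholesterol synthesis genes had a median of −1.50, with 16 of 18 lower and 0 higher. The Notch target Hes5 was 21.9-fold lower (17.9 to 26.6), Rgcc 28.7-fold, Adra2c 28.9-fold and Prss56 26.5-fold. The phototransduction list had a median of 2.29, and the photoreceptor genes Cdhr1 (111, 19.9 to 4390) and Abca4 (51.7, 9.28 to 2043) and Camk1d (40.4, 11.2 to 334) were among the highest under the limits set for named genes, but at resolution 0.4 the list median was −0.22 and the Abca4 log2 ratio −0.28. By size 1573 genes were higher and 1467 lower, against 372 and 206 in draws with no difference.

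Cell classes differed in their numbers relative to each other. Müller-like cells per rod-like cell were 30.1-fold higher in NaIO3 (20.0 to 47.5), with an interval of 9.28 to 15.7 at resolution 0.4, the lowest alternative. Neither class carries CD11b, but cells carried over through a bead selection need not keep the ratio of the classes. CD11b selection therefore cannot be excluded as a cause. The fold was 26.7 (18.0 to 41.2) among cells of at least 1500 UMIs and 800 genes, which argues against a loss of shallow barcodes for this class. For amacrine-like cells (2.79-fold, 1.83 to 4.32) that loss cannot be excluded, since at that depth the fold was 0.313 (0.114 to 0.749) with new clusters and 1.64 (1.02 to 2.67) with classes kept. Rod loss alone would raise all classes alike. Cone-like cells at 1.15-fold (0.958 to 1.39) and bipolar-like cells at 10.3-fold argue against it as the whole cause. At 5% mitochondrial UMIs, where 11 PBS cones were left, the cone-like fold was 10.2 (5.55 to 20.9). The Müller-like fold there was 17.0 (10.6 to 29.1), an overlapping interval, so rod loss alone is not excluded under that setting. In the other settings the cone-like and Müller-like intervals stayed apart. Microglia-like cells per Müller-like cell were 4.81-fold higher (2.34 to 10.3), and bead selection, dissociation and treatment cannot be told apart there, because selection is described for 1 library.

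Phototransduction genes were lower in NaIO3 rods, at a median of −0.75. A few genes taking most of the counts are excluded, since the median was −1.09 with TMM scaling (−1.11 to −1.07). Nuclear RNA in place of whole cells may account for part of it, since against PBS cluster 0 alone, with its low mitochondrial share, the median was −0.27 (−0.30 to −0.24), close to the limit of −0.3 set for that test. RNA shared with every class of the NaIO3 library stays open: the cone-like median, on which that test was set, was −0.95 (−0.98 to −0.93) but cannot read such RNA, since PBS cones held the list at 82308 CPM, and the bipolar-like median, looked at afterwards, was 1.46 but −0.76 at resolution 0.4. A biological difference between the treatments stays open and was not separated from these.

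Within the NaIO3 library, Il1b was higher in microglia-like cells above the median of 1960 UMIs than below it, at 137 and 13.6 CPM, a ratio of 10.1 (5.75 to 19.5), beside Tnf at 85.4, Ccl4 at 7.53, Ccl2 at 5.86, Nlrp3 at 2.69 and Cd36 at 0.979 (0.809 to 1.20). Counting depth is excluded as the whole cause, since at 1000 UMIs per cell 6.43% (4.87 to 8.30) of the deeper and 1.22% (0.398 to 2.83) of the shallower cells had an Il1b UMI. Dilution by free RNA is excluded too, since 5 microglial genes, C1qa among them, had a median log2 ratio of −0.016 against 3.33 for Il1b. Doublets with dendritic-like cells cannot be told apart, because 7 dendritic markers reached a median of 6.38% of their dendritic-like level where Il1b reached 16.4%. The deeper and shallower cells also came in part from different immune sub-clusters. Median depths of these, over both libraries, ran from 903 UMIs in sub-cluster 0 to 28809.5 UMIs in sub-cluster 4. A hypothesis that RNA-rich microglia-like cells are the ones that express cytokines was not tested and may be followed up with sorted cells. Cell size was not measured.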
